A study of Rattus norvegicus with 17 samples.

How the data were processed

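Gene expression was measured with an Illumina rat beadchip, an array whose beads carry 1 probe sequence each, in 17 RNA samples from male Sprague-Dawley rats. Alveolar type I (AT1) cells, the thin squamous cells that cover most of the gas exchange surface, were represented by 2 purified preparations. The other 15 samples had 1 array each: cells washed from the air spaces (bronchoalveolar lavage) and 14 tissues, namely liver, kidney, skin, salivary gland, duodenum, skeletal muscle, spleen, colon, trachea, ileum, testis, stomach, brain and heart. The labels give purities of 92% and 93% for the AT1 preparations without tying either value to an array. A treatment label common to all samples, tissues included, mentions cells that differentiate in culture, while other labels speak of RNA from primary tissue and purified AT1 cells. It is therefore unclear whether the AT1 cells were cultured before RNA extraction. Whole lung and isolated alveolar type II (AT2) cells, the surfactant-secreting cells of the same epithelium, were not analysed here.

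The scanner table held 22523 probes. Per the file headers, it gave the average bead intensity of each probe on each array, and the deposited intensities showed neither background subtraction nor normalization. Per the file headers, each intensity came with a detection p-value, and how that p-value was computed is not given in the sources used here. A second deposited table held the authors' processed values, which behaved as log2 intensities. Within each array their Spearman correlation with the scanner intensities was 1, and they rose by about 1.02 log2 units per log2 unit of bright signal. The submitters' processing notes name R 2.11.1, lumi and limma, without saying which step each performed, so the background correction and the normalization between arrays of that table stay unknown. Its column medians lay between 5.14 and 5.66.

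All values in the report were computed from the scanner intensities with R 4.3.3 and limma 3.58.1. The function neqc estimated the background from the detection p-values, added an offset of 16, applied quantile normalization and took log2. A probe counted as detected on an array at a detection p-value under 0.01, and the 15265 probes detected on at least 1 array were tested. Arrays detected between 7523 and 10084 probes, and the AT1 arrays 8448 and 8576. The number of arrays, with 1 per tissue, limits the precision.

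Probe names came from a table of the platform's annotation, with symbols updated through gene identifiers, of which 13752 were found in the reference gene table. Of all probes, 13793 had 1 gene symbol, 0 had several and 8730 had none. A probe without a symbol is unnamed here. Of the 13337 named genes, 425 had more than 1 probe, and a list used the probe with the highest mean over all arrays. The genome build of the array is not given in the sources used here, so no coordinates are printed.

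The main comparison set the 2 AT1 arrays against the other 15 arrays as 1 class with limma (lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05, two-sided). The residual spread was mostly that between tissues. A probe was called AT1-specific if it was detected on both AT1 arrays and its lower AT1 value exceeded every other array by at least 1 log2 unit (2-fold). A probe was called AT1-lowest if it was detected on all 15 other arrays and its higher AT1 value lay at least 1 log2 unit under each of them. Both counts were set beside those of the other pairs among all pairs of the 17 arrays, and for a single probe the lowest one-sided permutation p this allows is 0.00735. Where no array of a group detected a probe, the fold is a bound. The brighter group's mean was set against the dim group's mean of, per array, the higher of the probe's own value and the lowest value of a detected probe, and the result is written as "at least N-fold".

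Before the data were examined, 51 gene lists, the tests, the other settings to be tried and the rule for named genes were fixed. The rule took the 15 named AT1-specific and 10 named AT1-lowest genes with the largest margins among those past the adjusted threshold. It also took every AT1 marker with a probe, up to 4 members per other list with the largest difference, and the 10 largest differences each way against lavage cells. For each of the 4 tissues sharing most probes with AT1 cells it took the 4 genes with the largest margin, and for each tissue 1 marker. Genes added to complete a count of 5 or fewer were chosen after their values were seen and are said to be so. Of the lists, 37 describe cell types and pathways and were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the 37 lists. Of these, 1 list is not reported here but stays in the adjustment and the counts of lists and named genes. The other 14 lists hold tissue markers and served to check the labels. A count "adjusted over the list alone" corrects for the members of that list only.

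The AT1 arrays were alone on 1 of 3 slides, so slide and AT1 cells cannot be told apart. The other arrays filled a slide of 8 and a slide of 7, and the slide entered an alternative fit as a random block (statmod 1.5.0). The other settings tried were quantile normalization without background correction, median scaling, an offset of 50, the deposited log2 values, other detection filters, no intensity trend, a mean of its own per tissue, other margins, 1 slide of other tissues at a time, and leaving out each array in turn. Added after seeing the data were fits without the lavage and skeletal muscle arrays, and a fit with the AT1 mean as 1 array. Also added then was the lavage comparison without probes whose ileum value came within 2 log2 units of the lavage value or exceeded it.

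The scripts were tested on simulated data in which 200 of 15265 probes were changed between 2 AT1 arrays and the other 15. Of the changes of 2 log2 units 26% were called, and of those of 4 log2 units 76%, with median fitted changes of 2.03 and 4.02. Of the unchanged probes, 0 were called. The made AT1 arrays were drawn independently from each probe's mean and SD over the other arrays, whereas the real pair was closely alike. With no change and 1 drawn tissue value shared by both arrays, 0 probes were called too. Normal draws made probe by probe do not mimic a tissue whose genes move together, so these rates need not hold for the real data. Nothing in the labels says that the AT1 preparations came from separate animals, and p-values then measure only the spread between these samples, which for the AT1 arrays may be technical.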

Results

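The data compared the transcripts of purified rat AT1 cells with those of 14 tissues and of lavage cells, to find genes that set AT1 cells apart. The 2 AT1 arrays detected 8448 and 8576 of 22523 probes, within the range of 7523 to 10084 over all arrays. Across the 15265 probes tested, the AT1 arrays correlated with a Spearman coefficient of 0.966, 856 probes (5.61%) differed more than 2-fold between them, and 0 probes had identical scanner signals. Each tissue and the lavage cells had 1 array and therefore no replicate.

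Ager, the receptor for advanced glycation end products, stood farthest above all other samples, with a log2 signal of 14.96 ± 0.05 (SD, n = 2) in AT1 cells and 5.85 ± 0.95 (SD, n = 15) elsewhere. It was 133-fold above trachea, the next array (adjusted p = 1.36e-07). Akap5, a scaffold that anchors protein kinase A, reached 12.37 ± 0.26 against 5.12 ± 0.42 and was 59.1-fold above brain (adjusted p = 1.05e-09). Pdpn, the mucin-type glycoprotein podoplanin of the AT1 cell surface, was the brightest probe of both AT1 arrays, where quantile normalization sets the same value (15.09), and measured 11.41 in skin, the next array (adjusted p = 0.0041). Sftpc, the surfactant protein C that AT2 cells secrete, measured 13.56 ± 0.14 against 5.36 ± 1.36 and was 25.0-fold above trachea (adjusted p = 3.24e-05).

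The epidermal growth factor receptor ligands Areg and Hbegf rose by 5.60 and 5.69 log2 units. Areg was not above background in any other array and was at least 20.9-fold higher in AT1 cells (adjusted p = 5.1e-09), and Hbegf was 13.7-fold above trachea (adjusted p = 8.66e-05). The secreted axon guidance factors Sema3e and Sema3b were 17.7-fold above skin and 9.62-fold above kidney. Disp1, which releases lipid-modified Hedgehog proteins, was at least 9.56-fold above the other arrays, where it was not above background (adjusted p = 4.68e-08). Egfl6, a secreted protein with epidermal growth factor-like repeats, was 21.4-fold above kidney. Lmo7, a LIM domain protein of actin-linked cell junctions, was 23.8-fold above heart. Icam1, a leukocyte adhesion molecule, was 13.7-fold above lavage cells, and the retinoic acid-inducible receptor Gprc5a 15.1-fold above colon. The cytochrome P450 Cyp4b1 and the lipid-binding protein Sec14l3 were 13.9-fold and 13.2-fold above trachea.

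At the opposite end, Aif1, a calcium-binding protein of macrophages, measured 4.98 ± 0.05 (n = 2) in AT1 cells and 11.56 ± 1.32 (n = 15) elsewhere. It was not above background in either preparation and was at least 37.1-fold lower (adjusted p = 0.000169). The complement genes C1qb, C1qc and C1qa were at least 23.6-fold, 14.9-fold and 11.4-fold lower, and Ctss, a lysosomal protease of antigen-presenting cells, at least 19.8-fold lower. The beta globin gene Hbb-b1 was at least 61.7-fold lower (adjusted p = 0.000195). The globin genes Hbb and Hba-a1, however, measured 10.89 and 11.43 in AT1 replicate 1, so globin RNA was present in that preparation. The phospholipid transfer gene Pltp was at least 27.5-fold lower by 1 probe (adjusted p = 4.65e-05), while a second probe of the gene differed by -0.946 log2 units (adjusted p = 0.575). The endocytic adaptor Dab2 and the semaphorin receptor Plxnd1 were at least 18.9-fold and 10.3-fold lower. Fcer1g, a signalling subunit of Fc receptors, fell by 5.65 log2 units and was detected in 1 of 2 AT1 arrays. Without background correction the calls of C1qa and Dab2 ended (adjusted p = 0.0701 and 0.0882). The AT1 cells were purified, whereas the tissues hold many cell types. A low value therefore cannot tell a trait of AT1 cells from the removal of other cell types.

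**Figure D1:**
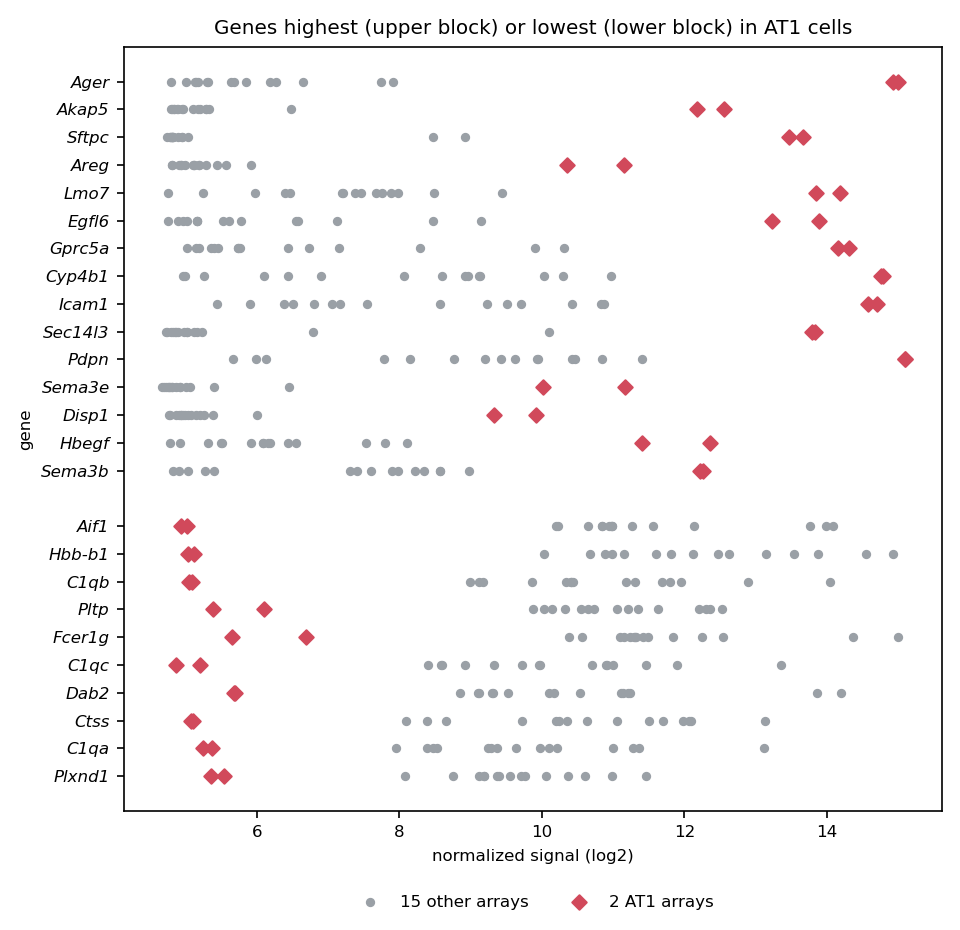
Normalized log2 signal (horizontal axis) of the named genes highest and lowest in AT1 cells (vertical axis), with 2 AT1 arrays as red diamonds and 15 other arrays as grey points. Ager lies at 14.96 on average in AT1 cells and at 7.90 in trachea, the next array, and Aif1 lies at 4.98 in AT1 cells and at 14.08 in lavage cells.

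In all, 835 probes (526 with a gene name) were higher and 176 (119 named) lower in AT1 cells at an adjusted p under 0.05 by limma, among 15265 tested. The fit counts the AT1 arrays, both of 1 cell type, as independent samples against a spread that is mostly between tissues. These counts and all adjusted p-values rest on that, and fewer probes were called with the AT1 mean as 1 array. At an unadjusted p under 0.05 the counts were 2003 and 768. Of the higher probes, 230 were above background in no other array, and of the lower probes 105 in neither AT1 array. The higher direction held 82.6% of the calls. This share depended on the background correction and scaling: it was 46.9% with median scaling (443 higher and 502 lower), 68.6% with the deposited log2 values (850 and 389), 87.8% with an offset of 50 (961 and 133) and 92.2% without background correction (1004 and 85). The median probe differed by -0.108 log2 units between AT1 cells and the rest, and by -0.757 with median scaling, so all differences are relative to that shift. With 1 AT1 array the counts were 186 higher and 22 lower without replicate 1, and 255 and 16 without replicate 2. Without testis they were 1174 and 277.

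AT1-specific probes numbered 305, of which 199 named a gene and 292 also passed the adjusted threshold. The lower AT1 value was at least 4-fold above every other array for 79 of them and at least 8-fold for 30, and 53 were above background in no other array. Whole lung and AT2 cells were not among the arrays to be exceeded, so AT1-specific cannot mean specific within the lung. Skin (41), brain (40), heart (28), trachea (25) and lavage cells (25) were most often the next array. The AT1 arrays are the only pair of 1 cell type, so a high count for this pair was largely set by the design. Of the pairs that join different samples, skeletal muscle with testis had 194, skeletal muscle with heart 155, liver with kidney 154 and spleen with lavage cells 154, and the median of all 135 was 4. The skeletal muscle array also held testis transcripts. The 135 include pairs of 1 AT1 array with another sample, which are kept low because the second AT1 array must be exceeded too. Taken singly, the AT1 arrays had 473 and 442 probes at least 2-fold above the 15 others. Among single tissue and lavage arrays, set against all 16 others, testis had 1883, brain 846 and liver 440, and the remaining 12 had between 41 (ileum) and 270 (skeletal muscle). In fits of 1 array against the other tissues and lavage cells, added after seeing the data, 202 probes were higher for the AT1 mean as 1 array, against 2210 in testis, 830 in brain, 327 in liver and between 2 (ileum) and 151 (skin) in the remaining 12. AT1-lowest probes numbered 74 (57 named), after 75 for testis with brain, and the median of the other pairs was 0. Many leading probes had no gene name, 22 among the 50 with the largest margin. With slide as a random block 989 probes were higher and 225 lower. Against the tissues of the slide of 8 alone, 508 probes were AT1-specific and 221 AT1-lowest. Against those of the slide of 7, which includes the lavage cells, the counts were 529 and 133, and 430 probes were higher and 49 lower. AT1-lowest probes numbered 117 without testis.

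**Figure D2:**
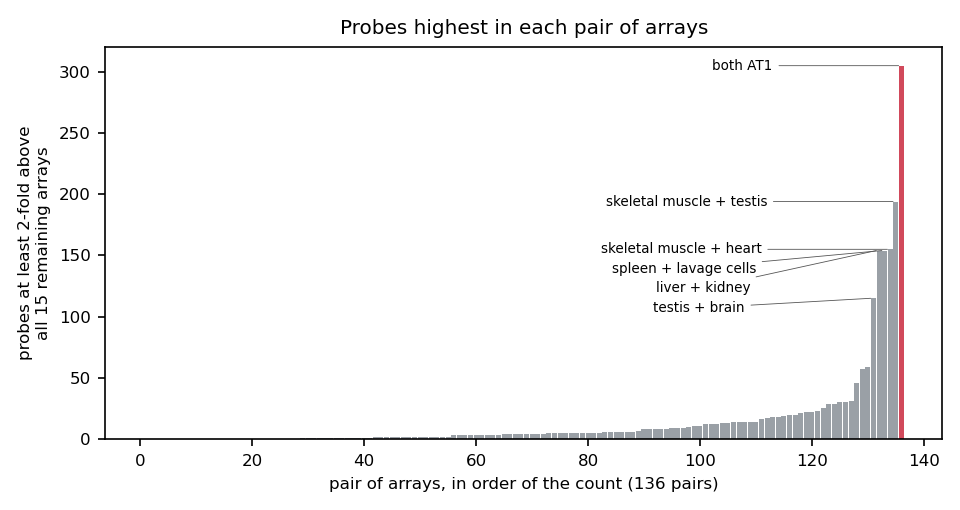
Number of probes at least 2-fold above all 15 remaining arrays (vertical axis) for each pair of the 17 arrays, ordered by that number (horizontal axis). Both AT1 arrays together stand at 305 and skeletal muscle with testis, the next pair, at 194.

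Of 27 AT1 markers with a tested probe, 22 rose, 0 fell and 19 were AT1-specific, with a median difference of 5.22 log2 units (camera adjusted p = 2.03e-32, and adjusted p = 7.13e-06 with an estimated correlation). Adjusted over the list alone, 24 rose. The list was drawn up from general knowledge of AT1 cells, which includes studies of this kind, and is not independent evidence of its direction. Besides the genes above, the water channel Aqp5 measured 14.19 ± 0.04 in AT1 cells and was 2.90-fold above salivary gland. The chloride channel protein Clic5 was 9.31-fold above skeletal muscle, the proteoglycan Spock2 4.46-fold above brain and the membrane protein Emp2 4.49-fold above skin. The basement membrane collagen gene Col4a3 was 5.77-fold above kidney, and the heparan sulfate proteoglycan Agrn 4.45-fold above skin. The angiogenic factor Vegfa was 4.41-fold above heart, the cell cycle inhibitor Cdkn2b 3.99-fold above stomach, the sodium channel subunit Scnn1g 3.15-fold above salivary gland and the activin antagonist Fstl3 measured 11.90 ± 0.08 against 10.31 in lavage cells, the next array. Krt7, a keratin of simple epithelia, was 2.19-fold above salivary gland, the metalloprotease inhibitor Timp3 on average 1.29-fold above kidney and Rtkn2 on average 1.13-fold above skeletal muscle. For both of these, 1 AT1 preparation lay below that tissue. The call of Rtkn2 ended with median scaling (adjusted p = 0.247).

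5 AT1 markers were not past the threshold. Hopx, a homeodomain protein, measured 14.98 ± 0.02 against 12.08 ± 1.48 (adjusted p = 0.101) and was detected in all 15 other arrays. Cav1, the main coat protein of caveolae, differed by 3.55 log2 units (adjusted p = 0.140), with an SD of 2.23 between the preparations, and its second probe by -0.407. Igfbp2, Col4a4 and Limch1 differed by 2.25, 0.71 and 0.55 log2 units. Gramd2, Cldn18 and Tspan36 were not analysed here.

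AT2 markers were high in the AT1 preparations as well. Of 11 tested, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 4.48 log2 units (camera adjusted p = 8.26e-10, and adjusted p = 0.048 with an estimated correlation). Among the 11, 5 counted as AT1-specific, which shows that this count takes in AT2 markers. The surfactant protein genes Sftpc, Sftpa1 and Sftpb rose by 8.20, 7.82 and 7.39, and the phosphate transporter Slc34a2 by 4.79. The lavage array held Sftpa1 at 11.37 and Sftpb at 9.89, next below the AT1 cells. Among 12 lung epithelium transcription factors 1 rose, Nkx2-1, the regulator of lung epithelial identity, which was at least 7.83-fold higher (adjusted p = 9.58e-08). The list had 2 higher members adjusted over the list alone and a median of 0.29, which turned to -0.37 with median scaling. Its adjusted p was 0.159 by camera and 0.038 by fry. Foxa2 differed by 5.63 (adjusted p = 0.0777; a second probe, not detected on any array, by 0.00168), Klf5 by 3.28 and Gata6 by 2.41.

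Markers of airway cells were not called as lists. For club cells, 0 of 7 members rose (1 adjusted over the list alone; list adjusted p = 0.328). Scgb1a1, the secretoglobin of club cells, measured 13.68 ± 0.02 in AT1 cells and was higher still in trachea, with a difference of 7.14 from the mean of all other arrays (adjusted p = 0.0554). Without the trachea array the list was called (adjusted p = 0.0248, median 1.12), and so was Scgb1a1. The list was also called against the slide of 8 alone (adjusted p = 0.00473, median 1.21), which had no trachea array. Bpifa1 differed by 3.23 and Scgb3a2 by 2.77, while Cyp2f4, a club cell cytochrome, differed by -0.92. Of 9 ciliated cell markers (adjusted p = 0.921) and 4 basal cell markers (adjusted p = 0.455), 0 rose and 0 fell, also adjusted over the list alone. Tppp3, the ciliated cell marker with the largest difference, measured 11.34 ± 0.23 in AT1 cells and 11.01 in trachea, the next array, and differed by 3.47 (adjusted p = 0.100), with a call without background correction (adjusted p = 0.0341). In AT1 cells the cilium genes Tekt1, Dynlrb2 and Spag6 were not above background in either preparation. The basal cell regulator Tp63, not above background there either, differed by -1.67 and was at least 1.36-fold lower.

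By camera, genes of alveolar macrophages, blood vessels and connective tissue were called lower in AT1 cells with the preset correlation but not with the estimated one. Fry also called the macrophage (adjusted p = 0.0436), endothelial (0.0343), fibroblast (0.0343) and smooth muscle (0.038) lists lower. As for the single genes above, this cannot tell a trait of AT1 cells from the removal of other cell types. Of 16 macrophage markers 3 fell, C1qb, Ctss and C1qa, and 0 rose (6 and 0 adjusted over the list alone), with a median of -2.21, or -1.47 with members not above background at their bound (camera adjusted p = 8.9e-05, but adjusted p = 0.287 with an estimated correlation). C1qb and C1qa were brightest in spleen (14.04 and 13.11) and measured 10.43 and 9.64 in lavage cells, so they are not particular to alveolar macrophages. Ctss was brightest in lavage cells (13.14). The lipid-binding protein Fabp4 differed by -5.40 (adjusted p = 0.0642), was not above background in either AT1 preparation and was at least 22.8-fold lower. Of 11 endothelial markers 4 fell and 1 rose (7 and 1 adjusted over the list alone; median -2.67, at the bound -2.06; adjusted p = 1.48e-05, and adjusted p = 0.273 with an estimated correlation). Plvap and Emcn, surface proteins of capillary endothelium, were at least 25.2-fold and 12.6-fold lower, and the receptor Tie1 at least 4.16-fold lower, with a difference of -1.35 at its second probe. The other member that fell was Sox17, by 2.67, named after its value was seen. The adhesion molecule Esam rose by 3.72 (adjusted p = 0.0058). Without background correction the calls of Plvap and Tie1 ended (adjusted p = 0.0597 and 0.067).

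Of 14 fibroblast and matrix markers 3 fell, also adjusted over the list alone, and 0 rose (median -2.70, at the bound -1.92; adjusted p = 1.48e-05, and adjusted p = 0.273 with an estimated correlation). The proteoglycan Lum was at least 17.5-fold lower and the growth factor receptor Pdgfra at least 6.67-fold lower, and the intermediate filament gene Vim, named after its value was seen, fell by 3.60. Of 6 smooth muscle markers 1 fell, Tagln, by 4.26, against 4 adjusted over the list alone (median -4.29, at the bound -4.08; adjusted p = 0.00038, and adjusted p = 0.273 with an estimated correlation). Actg2 and Des differed by -5.53 and -5.34, and Actg2, not above background in either AT1 preparation, was at least 29.2-fold lower. Leaving out 1 tissue raised the adjusted p of Lum to as much as 0.0667 and that of Tagln to 0.0573, with the call lost for 9 and 5 of the 15 arrays left out. Without background correction both calls ended (adjusted p = 0.173 and 0.131), as they did with an offset of 50 (adjusted p = 0.0908 and 0.0612). Lymphocyte markers had 0 calls among 17, also adjusted over the list alone (median -1.21, at the bound 0; adjusted p = 0.00844, and adjusted p = 0.688 with an estimated correlation). The T cell gene Cd3g differed by -3.11, but it was not above background in either AT1 preparation and was at least 3.31-fold lower. Of 7 neutrophil, 6 mesothelial and 5 erythroid markers only the globin gene Hbb fell, by 5.25, also adjusted over the list alone, with 1 AT1 preparation at 10.89 and the other at 5.83 (list adjusted p = 0.455, 0.719 and 0.159). Without AT1 replicate 1 the erythroid list was called (adjusted p = 0.0317). The mesothelial list had a median of -0.62 and a mean of 0.67, since the keratins Krt19 and Krt8 differed by 4.27 and 3.05.

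Genes of the basement membrane, the protein sheet on which epithelia rest, and of integrins were called higher as a list with the preset correlation. The list was also called by fry (adjusted p = 0.000204), but not with the estimated correlation. Of 12 basement membrane and integrin genes 4 rose (6 adjusted over the list alone) and 0 fell, with a median of 2.16 (adjusted p = 8.1e-06, and adjusted p = 0.0903 with an estimated correlation). They were Col4a3 (5.22), the laminin chain genes Lamb2 (3.89) and Lamb3 (3.14, named after its value was seen) and Agrn (3.76). The integrin gene Itgb6 differed by 4.95 (adjusted p = 0.0741). Of 16 genes of caveolae and membrane domains 4 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.39; adjusted p = 0.00169, and adjusted p = 0.483 with an estimated correlation). Emp2 rose by 4.38, and the caveola genes Cavin2 and Ehd2 by 3.70 and 3.64. The other calls, named after their values were seen, were Cavin1 with 2.48 and Emp3, which fell by 3.64. Of 18 general epithelial genes Krt7 and Tjp1 rose and 0 fell, also adjusted over the list alone (median 2.16; adjusted p = 0.000958, and adjusted p = 0.564 with an estimated correlation). The keratin Krt19, the adhesion molecule Epcam and the cadherin Cdh1 differed by 4.27, 3.49 and 3.25 without passing the threshold, and an intestinal array was the highest of the others for each.

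Of 17 tight junction and claudin genes 2 rose and 0 fell, against 3 and 0 adjusted over the list alone (camera adjusted p = 0.124). The list median of 0.31 turned to -0.60 with median scaling, -0.14 without background correction and -0.026 with an offset of 50. With the deposited values it was 0.69. Against the slide of 7 alone the list was called upward (adjusted p = 0.0197, median 1.55), and against the slide of 8 alone it was not (adjusted p = 0.360, median -0.16). The scaffold Tjp1 rose by 2.48, and the polarity gene Pard6b was at least 1.93-fold higher, a call that ended with median scaling (adjusted p = 0.0583). Of 16 water and ion transport genes 4 rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 0.117): Aqp5 by 8.10, Clic3 by 7.15, Clic5 by 6.29 and Scnn1g by 4.24. The sodium channel subunit Scnn1a differed by 6.04 (adjusted p = 0.0529). The median of this list was 0.29 and turned to -0.054 with median scaling, where the list was called upward (adjusted p = 0.0182), as it was without background correction (adjusted p = 0.0319) and without salivary gland (adjusted p = 0.0362).

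**Figure D3:**
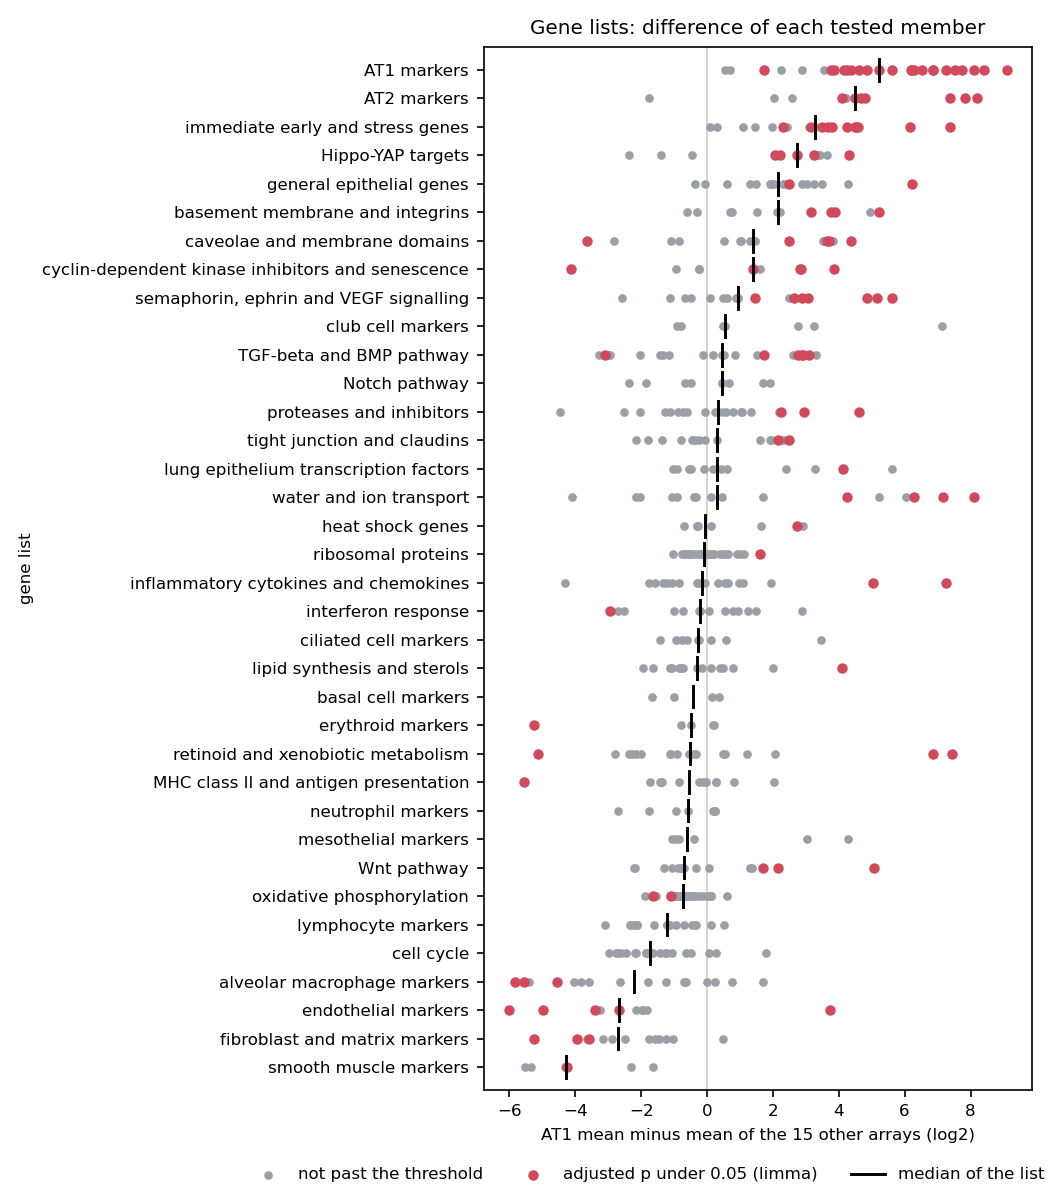
Difference of the AT1 mean from the mean of the 15 other arrays in log2 units (horizontal axis) for each tested member of 36 gene lists (vertical axis), with members past the adjusted threshold in red and the list median as a black bar. The AT1 marker median lies at 5.22 and the smooth muscle median at -4.29; medians within 1 log2 unit of 0 can change sign with the scaling, as for tight junction genes.

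Immediate early and stress genes, which cells switch on within minutes of a stimulus, were high in the AT1 preparations. Of 19 tested 11 rose, 0 fell and 7 were AT1-specific (13 and 0 adjusted over the list alone; median 3.29; adjusted p = 3.58e-11, and adjusted p = 0.128 with an estimated correlation). Atf3 rose by 7.36, Fos by 6.17, Jun by 4.58 and Egr1 by 4.53, and trachea was the next array for all of these, at a fold of 7.80, 3.05, 3.24 and 2.13. Of 11 Hippo-YAP targets 5 rose and 0 fell (7 and 1 adjusted over the list alone; median 2.74; adjusted p = 0.00169, and adjusted p = 0.273 with an estimated correlation). Ajuba rose by 4.30, while Ankrd1, F3 and Ccn1 differed by 3.63, 3.44 and 3.36 without passing the threshold. Ccn1 measured 9.02 and 14.23 in the AT1 preparations, against a mean of 8.27 elsewhere. Of 18 cytokine and chemokine genes the neutrophil attractants Cxcl1 and Cxcl3 rose by 7.25 and 5.04, also adjusted over the list alone, and Ccl5 differed by -4.32 (list adjusted p = 0.596). This list had a mean of 0.28 and a median of -0.16, which was 0.022 with the deposited values. Of 8 heat shock genes 1 rose, Hsp90aa1, by 2.72 (2 adjusted over the list alone; list adjusted p = 0.391; median -0.069, mean 0.73, and median 0.30 with the deposited values).

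Of 19 semaphorin, ephrin and VEGF genes 7 rose and 0 fell (11 and 1 adjusted over the list alone; median 0.94; adjusted p = 2.66e-06, and adjusted p = 0.0903 with an estimated correlation). Sema3e and Sema3b rose by 5.62 and 5.16, Vegfa by 4.87, and Sema3a was at least 4.02-fold higher than the other arrays, where it was not above background. Among 21 genes of the TGF-beta and BMP pathway 5 rose and 1 fell (6 and 3 adjusted over the list alone; median 0.45; list adjusted p = 0.455). Bmp4 rose by 3.09 and the endothelial receptor Acvrl1 was at least 6.63-fold lower, while Tgfb2 and Tgfb1 differed by 3.31 and -3.28 without passing the threshold. Among 15 Wnt pathway genes 3 rose and 0 fell, also adjusted over the list alone (median -0.69, mean 0.093; list adjusted p = 0.628). Wnt4 rose by 5.08. Wnt3a, detected in 1 of 2 AT1 arrays, was at least 1.48-fold higher, a call that ended with median scaling (adjusted p = 0.0969), and the other member was Wnt7a with 1.69, named after its value was seen. Of 9 Notch pathway genes 0 passed the threshold (1 rose and 2 fell adjusted over the list alone; list adjusted p = 0.921), with a median of 0.44 that turned to -0.54 with median scaling. Notch1 differed by -2.36 and Hes1 by 1.91. By limma, Lfng was called lower with median scaling (-2.60, adjusted p = 0.00508) and with the deposited values (-3.11, adjusted p = 0.00502). Notch1 was called lower with median scaling (adjusted p = 0.0199), and Jag1 higher without background correction (adjusted p = 0.0441).

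Of 9 cyclin-dependent kinase inhibitor and senescence genes 4 rose and 1 fell, also adjusted over the list alone (median 1.39; adjusted p = 0.0451, and adjusted p = 0.287 with an estimated correlation). Cdkn2b rose by 3.87, Cdkn1a by 2.85 and Cdkn1b by 2.83. The other calls were Cdkn1c with 1.39, named after its value was seen, and the binding protein Igfbp3, which was at least 9.74-fold lower, a call that ended without background correction (adjusted p = 0.0957). The list was not called with the deposited values (adjusted p = 0.282), against the tissues of the slide of 8 alone (0.159), with median scaling (0.0783, at a median of 0.37), with detection on at least 2 arrays (0.0654) or without a filter on dim probes (0.0588). It was also not called without brain (adjusted p = 0.105), skeletal muscle (0.0682), lavage cells (0.0571), testis (0.0557), salivary gland (0.0533), heart (0.0523) or duodenum (0.0509), without lavage cells and skeletal muscle together (0.0863, a fit added after seeing the data) or without AT1 replicate 2 (0.061). Of 21 cell cycle genes 0 passed the threshold by limma, also adjusted over the list alone, while the list as a whole was called lower (median -1.74, at the bound -0.82; adjusted p = 0.00139, and adjusted p = 0.671 with an estimated correlation). Rrm2, Ccna2, Cdk1 and Ccnb2, which serve DNA synthesis and mitosis, differed by -2.98, -2.78, -2.71 and -2.63, and Rrm2 and Ccna2 were not above background in AT1 cells.

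Of 33 oxidative phosphorylation genes 2 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.74; adjusted p = 1.48e-05, and adjusted p = 0.564 with an estimated correlation). The complex subunit gene Uqcrfs1 fell by 1.63, and the other was Atp5f1a, named after its value was seen, which fell by 1.08. With the deposited values the list was not called (adjusted p = 0.0805), and the call of Uqcrfs1 ended with the deposited values (adjusted p = 0.151), with median scaling (0.0861) and in 5 of the 15 fits without 1 array (up to 0.0545). Of 32 ribosomal protein genes 1 rose, Rplp2, by 1.60, against 0 adjusted over the list alone (list adjusted p = 0.591; median -0.10, mean 0.010, and median 0.26 with the deposited values). The call of Rplp2 ended with median scaling (0.87, adjusted p = 0.267), with the deposited values (adjusted p = 0.0542) and in 7 of the 15 fits without 1 array (adjusted p up to 0.0602). The antigen presentation list had 1 member that fell among 14, Ctss, also adjusted over the list alone (adjusted p = 0.199). The interferon list also had 1 among 16, Ifitm3, which fell by 2.95, also adjusted over the list alone (list adjusted p = 0.537), a call that ended in 9 of the 15 fits without 1 array (adjusted p up to 0.0558), with the deposited values (0.0654) and without background correction (0.0606).

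Of 20 retinoid and xenobiotic metabolism genes 2 rose and 1 fell, also adjusted over the list alone (median -0.52; adjusted p = 0.455). Cyp2b15 rose by 7.44 and Cyp4b1 by 6.86, while the glutathione transferase gene Gstm1 was at least 15.5-fold lower, a call that ended without background correction (adjusted p = 0.104). Of 15 lipid synthesis genes 1 rose, also adjusted over the list alone, Lpcat1, an enzyme of surfactant phospholipid synthesis, by 4.10 (median -0.29; list adjusted p = 0.537). Of 20 protease and inhibitor genes 3 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.455), with a median of 0.35 that turned to -0.32 with median scaling. Timp3 rose by 4.60 and Mmp11 by 2.95, the other was Prss8 with 2.25, named after its value was seen, and the protease inhibitor Slpi differed by -4.47 (adjusted p = 0.269). In all, 17 of the 37 lists were called by camera with the preset correlation, and AT1 and AT2 markers alone were called with the estimated one. Among the called lists reported here, fry did not call the lymphocyte (adjusted p = 0.463), general epithelial (0.192), cell cycle (0.382) and oxidative phosphorylation (0.287) lists. Of 80 named genes with a call, 50 lost it without AT1 replicate 1 and 49 without replicate 2, and 28, Ager, Akap5 and Sftpc among them, kept it in both fits.

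Against lavage cells, the other sample from the air spaces, AT1 cells held Spock2 at least 298-fold higher, Aqp5 at least 220-fold, Egfl6 at least 142-fold, Cxcl1 at least 132-fold, Cav2 at least 81.4-fold and Akap5 at least 62.3-fold. Lmo7, the adhesion protein gene Flrt3, Clic5 and Ager were 188-fold, 164-fold, 159-fold and 149-fold higher. In the other direction Fcer1g, detected in 1 of 2 AT1 arrays, measured 14.99 in lavage cells and 6.17 ± 0.73 in AT1 cells. Aif1, the lysosomal membrane gene Laptm5, the chemokine Ccl6, the survival gene Bcl2a1 and the matrix protein Spp1 were at least 213-fold, 208-fold, 198-fold, 165-fold and 146-fold higher in lavage cells. The remaining 4 of the 10 largest differences were intestinal genes: the ileal bile acid carrier Fabp6 (at least 289-fold), the Paneth cell defensin Defa9 (at least 230-fold), the antibacterial lectin Reg3g (at least 183-fold) and the goblet cell lectin Zg16 (at least 153-fold). Each of these was higher still in the ileum array, for example Reg3g at 15.01 there and 13.86 in lavage cells.

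Among 9740 probes detected in lavage or in both AT1 arrays, 427 were at least 8-fold higher in AT1 cells and 702 in lavage cells, and 2118 and 2055 at least 2-fold. Across all 15265 probes tested, which are not independent replicates, the Spearman correlation of the AT1 mean with lavage cells was 0.725. Without probes whose ileum value came within 2 log2 units of the lavage value or exceeded it, 274 probes were at least 8-fold higher in lavage cells. That setting was added after seeing the data. Macrophage markers were a median of only 1.93 log2 units higher in lavage cells than in ileum (16 genes). The setting can therefore also remove genes of the lavage cells themselves, and 274 is not a count freed of ileal transcripts alone. With 1 lavage array this comparison had no test.

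High expression was shared with 1 other tissue by 147 probes, detected and at least 2-fold above the 14 remaining arrays in both AT1 arrays and that tissue. Testis shared 32, brain 31, trachea 15 and liver 12, and skeletal muscle and ileum shared 0. Taken singly, testis (1883) and brain (846) also had the most probes above all other arrays and ileum (41) the fewest. The shared counts therefore do not measure similarity to AT1 cells. Some shared probes were AT1-specific too, such as 4 of those with trachea. With testis, AT1 cells shared C7h12orf56, Misp3, the transporter Abca5 and Btbd16, which was brighter in testis (12.33) than in AT1 cells (9.06 ± 0.31). With brain they shared the imprinted gene Nnat (9.40 in brain and 8.88 ± 0.16 in AT1 cells), Spock2 (12.47 and 14.63 ± 0.24), the semaphorin Sema4f (11.60 and 11.49 ± 0.04) and Lgi3. With trachea they shared Cxcl1, Sec14l3, Fos and Atf3, of which Cxcl1 measured 12.78 in trachea and 13.45 ± 0.62 in AT1 cells. With liver they shared the fibrinogen gene Fgg (14.83 and 11.27 ± 0.25), Cyp2b15 (13.32 and 14.78 ± 0.01), the sulfotransferase Sult1a1 and Slc34a2. The skeletal muscle array also held testis transcripts, so probes shared by AT1 cells, testis and muscle are not in the testis count. With a margin of 0 the total was 1893 and with 2 log2 units 30.

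The 14 tissue marker lists were each highest in the array of their own tissue. Liver markers averaged 14.28 in liver and 7.21 in kidney, the next array, and brain markers 12.38 in brain and 6.17 in stomach. The fibrinogen gene Fgb was at least 505-fold above the next array in liver, Snap25, a synaptic vesicle fusion protein, 110-fold in brain and Slc34a1, a renal phosphate transporter, at least 99.5-fold in kidney. The acid pump gene Atp4a, the brightest probe of the stomach array, measured 7.68 in liver, the next. Stomach markers averaged 14.52 in stomach and 9.19 in liver, also the next array for that list. The salivary gene Smr3b was at least 108-fold above the next array and the sperm protamine gene Prm2 at least 71.8-fold. The muscle myosin gene Myh4 stood 52.8-fold higher in skeletal muscle, the alkaline phosphatase Alpi 30.6-fold in duodenum, the complement receptor Cr2 23.5-fold in spleen and the heart myosin light chain Myl2 8.30-fold in heart. Cartilage collagen Col2a1 measured 10.22 in trachea and was not above background elsewhere, Hoxb13 was at least 10.4-fold higher in colon, Krt14 6.41-fold in skin and the bile acid transporter Slc10a2 at least 5.38-fold in ileum. The next array for ileum markers was lavage cells (10.17 and 8.28), and that for testis markers was skeletal muscle (14.42 and 10.02). Without both arrays, a fit added after seeing the data, 827 probes were higher and 173 lower in AT1 cells, 338 were AT1-specific and 99 AT1-lowest.

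**Figure D4:**
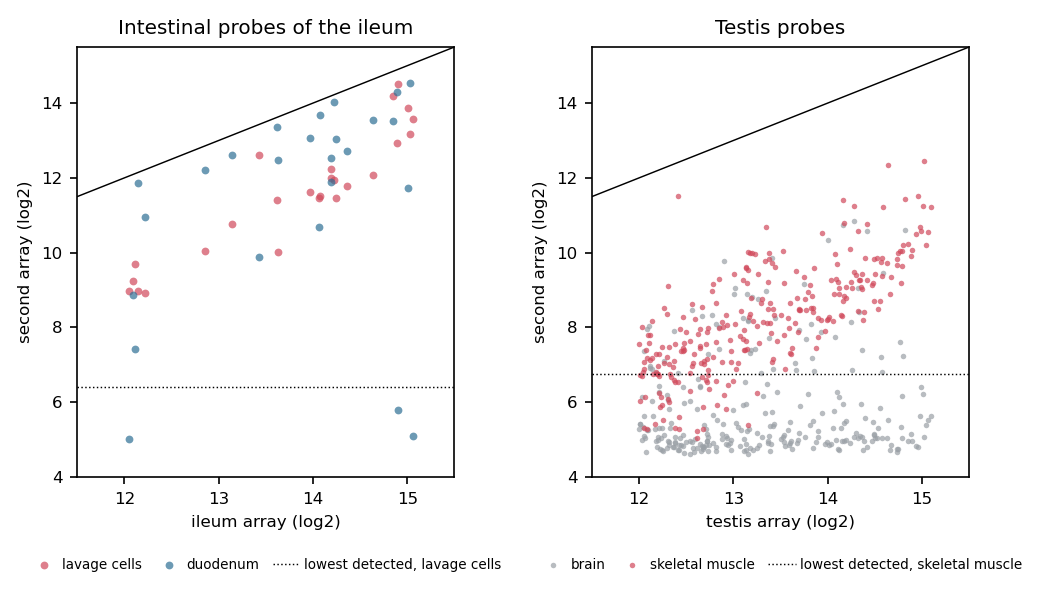
Left, log2 signal of 25 bright intestinal probes in the ileum array (horizontal axis) and in the lavage or duodenum array (vertical axis). Right, 273 bright testis probes in the testis array (horizontal axis) and in the skeletal muscle or brain array (vertical axis); solid lines mark equal signal and dotted lines the lowest detected signal, above which lie 100% of the ileal probes in lavage cells and 84.2% of the testis probes in skeletal muscle.

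By Spearman correlation with the AT1 mean across probes, salivary gland (0.767), stomach (0.756) and kidney (0.752) were closest to AT1 cells and testis (0.474) farthest. Ileum correlated with duodenum at 0.924 and with lavage cells at 0.868.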

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

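The settings tried were fixed before the data were examined, apart from those named next. Chosen after seeing the data were the fits without the lavage and skeletal muscle arrays and with the AT1 mean as 1 array. The lavage comparison without probes near or above their lavage value in ileum was also chosen then. The AT1 marker list was called higher in all 29 alternatives run on it, with medians between 3.57 and 6.58 log2 units. The tissue lists were checked again with the deposited values only, where all 14 stayed highest in their own tissue.

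Counts moved more. Without background correction 85 probes were lower and 21 AT1-lowest. Of those, 81 and 21 were among the 176 and 74 of the report; uncorrected background narrows every difference near it. Median scaling gave 443 higher, 502 lower and 149 AT1-lowest probes, turned the water and ion transport median to -0.054, and shared 428 higher and 172 lower probes with the report. The deposited values gave 389 lower probes, sharing 160, and 850 higher probes, sharing 596. Leaving out 1 array at a time, the higher count lay between 186 (without AT1 replicate 1) and 1174 (without testis), the lower count between 16 (without AT1 replicate 2) and 277 (without testis), the AT1-specific count between 309 (without duodenum) and 473 (without AT1 replicate 2), and the AT1-lowest count between 74 and 117 (without testis). Without AT1 replicate 2 the higher count was 255, and without AT1 replicate 1 the lower count was 22 and the AT1-specific count 442. The lone AT1 array was then assumed to vary like the other samples. Against the tissues of 1 slide alone, 508 and 529 probes were AT1-specific and 221 and 133 AT1-lowest, which fewer arrays to exceed allow, and the slide of 7 gave 430 higher and 49 lower probes.

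Without a filter on dim probes 1538 were higher. A mean of its own for each tissue, which leaves the gap between the AT1 arrays as the only spread, gave 3682 higher and 4791 lower. Counting the AT1 mean as 1 array gave 202 higher and 20 lower. A margin of 0 gave 1228 AT1-specific and 243 AT1-lowest probes, and 2 log2 units gave 79 and 21. For probes shared with 1 tissue these margins gave 1893 and 30. With an estimated correlation 2 lists were called, against 17. The lavage comparison had 702 probes at least 8-fold higher in lavage cells. Without those within 2 log2 units of the lavage value, or above it, in ileum, 274 remained, and this setting can remove lavage cell genes too. Counts stayed within 1.5 times those of the report with an offset of 50 (961 higher, 133 lower), without the lavage array (839 and 187), with slide as a random block (989 and 225, at a consensus correlation of -0.0504), without an intensity trend (869 and 175) and with detection on at least 2 arrays (743 and 183). The cause of the remaining shifts was not tested.

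Among 168 named genes, calls lost and gained numbered 10 and 9 without background correction, 5 and 11 with median scaling, and 3 and 9 with the deposited values. Besides those named in the report, the call of Myl9 ended without background correction (adjusted p = 0.195). With an offset of 50 it ended too (adjusted p = 0.0857), as did those of Lum and Tagln. Among genes short of the threshold in the report, Scnn1a, Itgb6 and Foxa2 gained a call without background correction (adjusted p = 0.0137, 0.0189 and 0.0396), and Notch1, Tgfb1 and Fabp4 with median scaling (adjusted p = 0.0199, 0.0255 and 0.0278). Signal over background limited the lower side most, where 105 of 176 probes have a bound instead of a fold. No paired analysis was possible because the AT1 replicate numbers have no counterpart in tissues with 1 array. The AT1 marker list without Gramd2 was not run as a separate count, since no probe was named for that gene.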

Other observations

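The tests of ileum RNA in the lavage sample, of ileal genes in the lavage cells themselves, of AT2 cells and of both explanations of the immediate early genes were chosen only after related results were seen, and the ileal probe set after a first, narrower set had been looked at. The bound for the handling test was set anew after its value was seen. The genes of the next paragraphs were chosen after their values were seen.

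AT1 cells and heart shared several genes. Crip2, a LIM domain protein, measured 14.68 ± 0.005 in AT1 cells (n = 2) and 14.41 in heart, and no other array exceeded 12.50. Cavin1, which shapes caveolae, measured 7.96 ± 0.14 and 7.65, and the neurotrophin Bdnf 10.48 ± 0.42 and 9.71. Vegfa was at 12.91 ± 0.13 in AT1 cells and 10.77 in heart. With salivary gland AT1 cells shared the water channel Aqp5 (14.19 ± 0.04 and 12.66) and the sodium channel subunits Scnn1b (12.35 ± 0.03 and 12.58) and Scnn1g (10.35 ± 0.38 and 8.69), and with kidney the basement membrane gene Col4a3 (10.42 ± 0.23 and 7.89). With skin they shared Flrt3 (13.84 ± 0.17 and 11.77) and the annexin Anxa8 (13.84 ± 0.12 and 12.70).

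The AT1 preparations differed at least 8-fold at 5 probes, all named. RT1-A2, a class I MHC gene of a region that varies between rat strains, measured 4.97 in replicate 1, where it was not detected, and 11.30 in replicate 2. The globin genes Hba-a1 and Hbb measured 11.43 and 10.89 in replicate 1 and were not detected in replicate 2. The matrix protein gene Ccn1 measured 9.02 and 14.23, and Cav1 9.74 and 12.89. Among probes without a gene name, the largest margin over the next array was 5.80 log2 units, for a probe at 14.45 ± 0.10 in AT1 cells and at most 8.58 elsewhere (trachea; adjusted p by limma = 2.21e-06).

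Genes of one tissue appeared in the array of another. Of 25 bright intestinal probes of the ileum, 100% were detected in the lavage array, at a median of 2.37 log2 units below ileum, against 64.0% and 7.60 units in trachea and 59.2% and 3.32 units in spleen (49 probes). Of 273 bright testis probes 84.2% were detected in skeletal muscle, against 34.9% in trachea, the next array for testis. Such a share was not unique: over all pairs of arrays with at least 10 such probes, 100% of 26 skeletal muscle probes were detected in trachea and 94.7% of 19 lavage probes in spleen, with a median of 21.8% for the pairs other than testis with muscle. Of 13 bright stomach probes 69.2% were detected in liver. The gap between ileum and lavage was more even, with an interquartile range of 0.824 log2 units against 2.70 between ileum and duodenum. Gut regions differ strongly at some of these probes, such as Fabp6 at 14.90 in ileum and 5.79 in duodenum, which widens the second range. Own expression of ileal genes by lavage cells is therefore not decided by this comparison. An exchange of whole samples is argued against by macrophage markers 1.93 units higher in lavage than in ileum (16 genes) and by muscle markers 8.62 units higher in muscle than in testis (7 genes). RNA of ileum in the lavage sample and of testis in the muscle sample, at about 2.85% of the testis level, stays a candidate explanation, and no biological explanation was tested beyond the expression of ileal genes by lavage cells.

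AT2 genes were abundant in the AT1 preparations, with Sftpa1 at 13.65 ± 0.09 and Sftpc at 13.56 ± 0.14. Residual AT2 cells may account for this, since neither preparation was fully pure, but expression by AT1 cells stays open too. If such cells set the level, AT2 markers might move together between the preparations, and the median gap was -0.148 log2 units over 11 genes, with 7 lower in replicate 2 and a typical replicate SD of 0.173. Preparations of near-equal purity would give the same small gap, so both explanations cannot be told apart without AT2 cells or whole lung.

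Immediate early genes were high in AT1 cells and in trachea. A response of living cells to handling, shared by the lavage cells, stays open. In the lavage array the list lay 0.711 log2 units above the mean of the 14 tissues, with an interquartile range of 1.25 over 19 genes, and 17 of these genes lay below AT1 cells. A weaker response in lavage cells would give such values, and that single array also held ileal transcripts. Digestion of the lung during isolation may raise such genes, but trachea, a tissue array, came within a median of 0.653 units of the AT1 cells, against 2.57 in skin, the next. Whether the AT1 cells were cultured before RNA extraction is unclear from the labels, and culture might change these genes too. Handling, digestion and a resting level common to airway and alveolus cannot be told apart here, since no digested control or intact lung was analysed here.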
